A study of Mus musculus with 6 samples.

How the data were processed

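RNA sequencing was done on cultured cortical neurons taken from the neocortex of mouse embryos at embryonic day 14 and plated in 35 mm dishes. The 6 libraries fall into 3 groups of 2 replicates each: wild type after 1 day in vitro (DIV1), wild type after 3 days in vitro (DIV3), and, per the labels, Ptbp2 knockout at DIV1. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, and made into stranded total RNA libraries with an Illumina TruSeq kit. The design text calls the 2 libraries of a group biological replicates. It does not say whether they came from separate embryos, litters or culture days, so p-values measure only the spread between these libraries. The sex-linked genes, given below, show that the 2 libraries of each group came from embryos of different sex.

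The deposited values are expected counts, that is, estimated read counts per gene and per transcript that need not be whole. Per the submitters' processing notes, STAR and RSEM were used with the mouse build GRCm38 (mm10); the versions and the annotation release are not given in the sources used here. The expected counts are not scaled for depth or length, and replicates were not pooled. RSEM splits reads shared by several transcripts in proportion to its model. The uncertainty of that split is not in the deposited tables, so none of the tests carries it, and genes with near-identical copies, such as the globins and the tubulins, are less certain than others. The deposited tables hold 49671 genes and 123063 transcripts. Gene and transcript names, exon counts, lengths and coordinates were taken from the GENCODE M21 annotation of GRCm38 by identifier without version, which matched 99.5% of the genes and 99.4% of the transcripts. For 99.5% of the genes with matched transcripts, the transcript counts added up to the gene count within 1 count.

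Totals per library were 47044778 and 49017376 expected counts in wild type at DIV1, 75522198 and 39104879 in wild type at DIV3, and 53372137 and 71461054 in the knockout. Mitochondrial genes took between 1.46% and 1.96% of the counts. A chi-square comparison of counts over genes gave 21.9, 18.1 and 74.1 per gene for the pairs of wild type at DIV1, wild type at DIV3 and knockout, so no pair was a library deposited more than once.

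Expected counts were rounded to whole numbers for the tests. Genes were kept by edgeR's filterByExpr (minimum count 10), scaled by TMM (factors from 0.95 to 1.04), and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with all 6 libraries in the same fit, which leaves 3 residual degrees of freedom. The 2 contrasts were wild type at DIV3 against wild type at DIV1, and knockout against wild type at DIV1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of its F statistic. Levels are given as CPM, counts scaled to the library total with TMM factors.

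Isoform usage was tested on the transcript table. Transcripts were kept by filterByExpr and a mean share of at least 5% of their gene in at least 1 group, in genes with 2 or more such transcripts. The test was edgeR's diffSpliceDGE with the Simes gene-level p, and a gene was called at an adjusted p under 0.05 with at least 1 transcript whose mean share differed by 10 percentage points or more. Shares are percentages of the gene's expected counts.

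A set of 31 gene lists was written from background knowledge before the data were examined. It covers axon specification and growth, axon guidance, the axon initial segment, the neuronal cytoskeleton, synapses, ion channels, splicing regulators, progenitors and the cell cycle, cortical neuron types, other cell types, stress and growth responses, mitochondrial and sex-linked genes, and genes with exons known to be regulated in neurons or by polypyrimidine tract binding proteins. The lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each Benjamini-Hochberg adjusted over the 31 lists. Camera compares a list with all other genes. Fry tests whether a list's genes move, on balance, one way. The designs, the alternatives and the rule for named genes were also fixed before the data were examined.

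Named genes are Ptbp2 and Ptbp1. They are also, per contrast, the 8 called genes with the largest increase and the 8 with the largest decrease among genes with a mean of at least 5 CPM, leaving out predicted, clone-based, pseudogene, small RNA and mitochondrial names. Per list, up to 3 called members with the smallest adjusted p and the most abundant member that did not pass are named. For isoforms, the rule takes the 12 called genes with the largest share change among genes with at least 100 mean expected counts, up to 8 called members of the list of regulated exons, Shtn1 and Dlg4 whether called or not, and up to 12 genes called in both contrasts. Genes outside the rule are said to be chosen after their values were seen. A few genes that the rule takes are not reported here.

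Both contrasts use the same 2 wild-type DIV1 libraries. The relation between them was therefore set beside 100 simulated data sets with no change in any group. These gave every library the dispersion estimated over all 3 groups. A tally of directions over the list of regulated exons was added after the data were seen. The main gene-level test and the Simes, F and limma isoform tests were tested on simulated data with 200 changed genes. The list tests were not. At gene level, 1.5-fold, 2-fold and 4-fold changes were recovered in 38.8%, 80.6% and 100% of cases for the DIV3 contrast, with 17 unchanged genes among 163 calls. For the knockout contrast they were recovered in 32.8%, 83.6% and 100%, with 24 unchanged genes among 168 calls. In both contrasts the share of unchanged genes among these calls was above the nominal 5%. For isoforms, the first setting tried placed 2-fold and 4-fold changes of a transcript in genes with at least 100 counts, at the dispersion estimated from these libraries. The Simes test recovered 0% of either fold in both contrasts, and its 15 calls for DIV3 and 4 for the knockout were all unchanged genes. After that result was seen, larger changes, higher counts and a lower dispersion were simulated to tell low power from an error in the test. In this later setting, 4-fold and 10-fold changes were placed in genes with at least 1000 counts. With a low dispersion of 0.01, the Simes test recovered 96% and 100% for DIV3 and 100% and 100% for the knockout. With the dispersion estimated from these libraries it recovered 5% and 39% for DIV3 and 3% and 35% for the knockout. Of its 60 calls for DIV3 and 54 for the knockout at the estimated dispersion, 16 and 16 were unchanged genes, above the nominal 5%. At that dispersion the F test recovered 31% and 73%, and limma's diffSplice 36% and 78%, for DIV3. For the knockout these were 30% and 78%, and 36% and 82%. In the simulated data sets with no change, a mean of 6.26 genes for DIV3 and 6.32 for the knockout were called for isoform usage, at most 16 and 19, and a mean of 1.35 and 1.51 genes were called at gene level.

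Alternatives tried were DESeq2 1.42.0, limma-voom, RLE size factors, library totals with no TMM, no filter, a stricter filter of 1 CPM, only the 4 libraries compared, the replicate number as a block, a minimum fold of 1.5, and leaving out each library in turn. For isoforms they were the F test, limma's diffSplice, other share limits of 0 and 20 points, other transcript filters, the block and leaving out each library. Leaving out a library leaves a group with 1 sample, which is then assumed to vary like the other groups. The block adds a single replicate term shared by all 3 groups, which leaves fewer residual degrees of freedom. After the data were seen, fits were added that remove the trend with transcript length, or with length and GC content, from each library by loess (span 0.3). A limma test on log ratios of transcript shares was also added, and so was the gene-level relation over genes with a mean log2 CPM above 2. The length fits had 16795 genes, since 52 had no length. Neither these fits, the log-ratio test, DESeq2 nor gene-level limma-voom was run on the simulated data with changed genes. Their power and error rates here are therefore not known. DESeq2 left 2287 adjusted p-values of the knockout contrast undefined, and these were not counted as calls or as lost calls.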

Results

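Transcripts were measured in mouse cortical neurons in culture, before and during the interval in which a neurite becomes the axon, and in neurons labelled knockout for Ptbp2, the gene of the splicing regulator polypyrimidine tract binding protein 2 (PTBP2). Wild-type neurons were sampled at DIV1, when the neurites cannot be told apart, and at DIV3, when axon growth has begun. The neurons labelled Ptbp2 knockout were sampled at DIV1. Each of the 3 groups had 2 libraries, with totals between 39104879 and 75522198 expected counts per library. On the first principal component, with 69.2% of the variance, the DIV3 libraries lay at 71.4 and 65.5, the wild-type DIV1 libraries at -22.2 and -26.4, and the knockout libraries at -54.3 and -34.0. The knockout libraries differed from each other more than the wild-type pairs did. The SD of the log2 difference between replicates over genes was 0.34 in the knockout, against 0.18 in wild type at DIV1 and 0.20 at DIV3.

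That difference went with transcript length. Across genes, which are not independent replicates, the log2 difference between replicates 1 and 2 had a Spearman correlation with length of -0.68 in the knockout, 0.41 in wild type at DIV1 and 0.51 at DIV3. When 11262 genes were ordered by length into 5 groups of 2252 or 2253, in the group with the shortest transcripts (median 1252 nt), the median difference was 0.29 in the knockout, and in that with the longest (median 6440 nt) it was -0.26. The group comparisons carried the trend too. From the shortest to the longest group, the median log2 fold change of knockout against wild type went from 0.24 to -0.21, and that of DIV3 against DIV1 from -0.10 to 0.14.

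**Figure D1:**
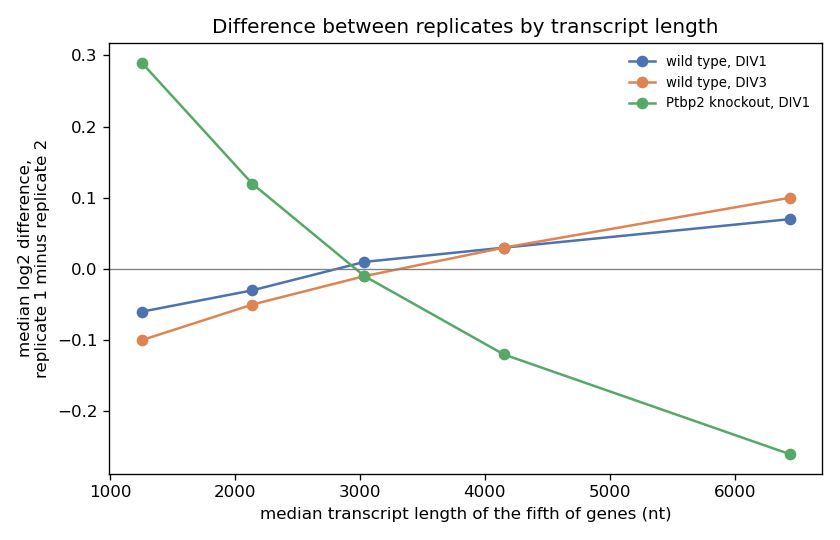
Median log2 difference between replicate 1 and replicate 2 (vertical axis) for 5 groups of genes ordered by transcript length (horizontal axis, median length in nt), with a line per group. The knockout line falls from 0.29 to -0.26, while the wild-type lines rise from -0.06 to 0.07 at DIV1 and from -0.10 to 0.10 at DIV3.

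Ptbp2 (chromosome 3, 119718742 to 119784466, GRCm38), the targeted gene, was measured at 465 and 429 CPM in wild type at DIV1, 403 and 382 CPM at DIV3, and 474 and 514 CPM in the libraries labelled knockout. Its log2 fold change was 0.14 ± 0.09 (SE) in the knockout (adjusted p = 0.413, edgeR quasi-likelihood test, Benjamini-Hochberg; 0.21 ± 0.07 with the length trend removed) and -0.19 ± 0.09 from DIV1 to DIV3 (adjusted p = 0.158). A count over the whole gene does not check the label where a deletion removes an exon and leaves the rest of the transcript, so knockout denotes the label alone. The share of the transcript Ptbp2-213, chosen after its values were seen, was 48.7% ± 4.22 (SD, n = 2) in wild type at DIV1 and 19.8% ± 8.69 in the knockout, while that of Ptbp2-201 was 46.7% ± 4.73 and 78.2% ± 9.91. The Ptbp2 isoform difference did not pass the test (adjusted p = 0.312, edgeR diffSpliceDGE, Benjamini-Hochberg). Ptbp1 (chromosome 10, 79854427 to 79864771), the paralog that is abundant in progenitors, fell from 163 ± 6.47 CPM (SD, n = 2) at DIV1 to 110 ± 4.86 CPM at DIV3. Its log2 fold change was -0.57 ± 0.09 (adjusted p = 0.00276, edgeR quasi-likelihood test, Benjamini-Hochberg), against 0.01 ± 0.08 in the knockout (adjusted p = 0.967).

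The first comparison asked which genes change in wild-type neurons over the interval of axon formation. Genes of the axonal cytoskeleton and of synapses rose. Mapt, which encodes tau, rose from 798 ± 40.7 CPM (SD, n = 2) at DIV1 to 2398 ± 59.8 CPM at DIV3. Gap43, a growth cone protein, rose from 408 ± 27.3 to 895 ± 75.1 CPM, and Nefl, the neurofilament light chain, from 31.5 ± 2.21 to 216 ± 10.9 CPM. Eomes, a transcription factor of intermediate progenitors, fell from 256 ± 3.36 to 110 ± 2.5 CPM, and the stress gene Trib3 from 2.61 ± 0.113 to 0.581 ± 0.0219 CPM. Of 16847 genes tested, 3328 were higher and 2760 lower at DIV3 (6088 genes, 36.1%) by the edgeR quasi-likelihood test, and 1197 and 856 of them changed by 2-fold or more. With library totals in place of TMM, the split was 2563 higher and 3996 lower, 39.1% higher against 54.7%, and the median log2 fold change of all genes was -0.13. The count was 2959 without wild-type DIV1 replicate 1, 2743 without wild-type DIV1 replicate 2, 2954 without DIV3 replicate 1 and 3408 without DIV3 replicate 2.

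**Figure D2:**
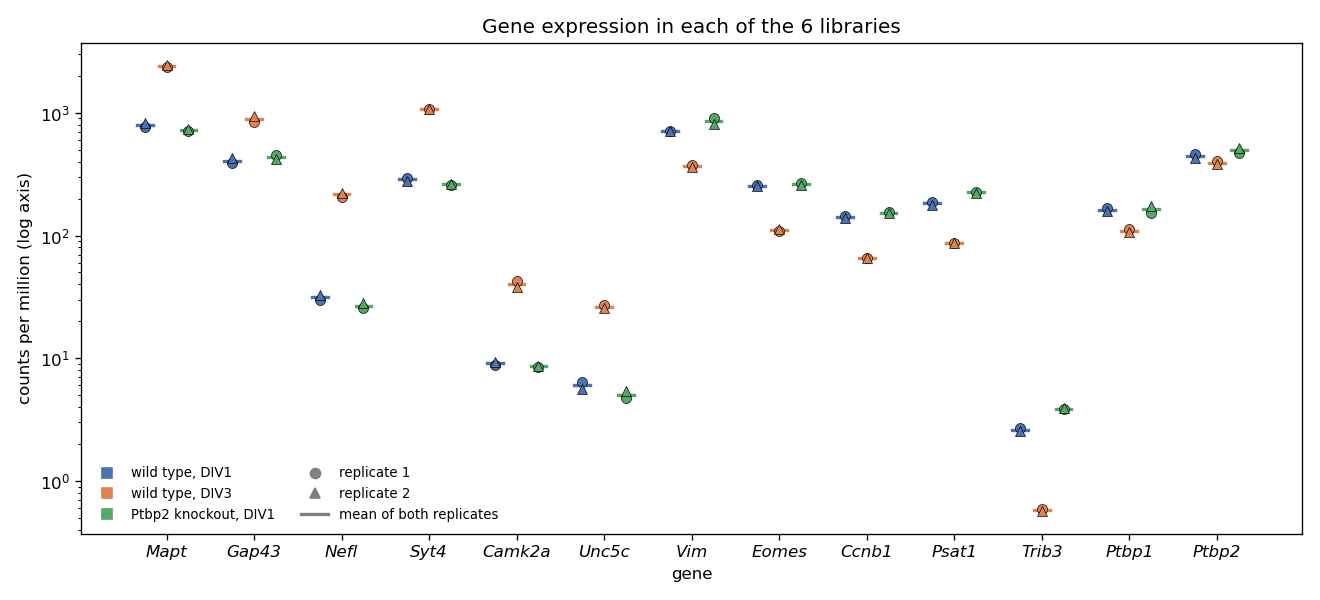
Expression of 13 named genes in CPM, counts scaled to the library total (vertical log axis) in each of the 6 libraries, with colours for groups, symbols for replicates and a line for the mean of both replicates. Mapt rose from 798 to 2398 CPM and Eomes fell from 256 to 110 CPM between DIV1 and DIV3 in wild type, while Ptbp2 lay between 382 and 514 CPM in the 6 libraries.

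Neuronal lists rose at DIV3, except those of deep-layer and Cajal-Retzius markers, which did not pass. Where no count adjusted over the list alone is printed for a list of this comparison, it equalled the count over all genes. Among neuronal microtubule and neurofilament genes, 20 of 21 measured members rose and 1 fell. Nefl had a log2 fold change of 2.78 ± 0.09 and Nefm of 1.68 ± 0.11 (adjusted p = 5.23e-05 and 0.000164, edgeR quasi-likelihood test, Benjamini-Hochberg). The list had a camera adjusted p = 6.93e-14, and an adjusted p = 0.106 with an estimated correlation. Of 34 genes of axon specification and growth, 19 rose and 3 fell (20 and 4 adjusted over the list alone). Besides Mapt (1.59 ± 0.10) and Gap43 (1.13 ± 0.11), Nrcam, a cell adhesion molecule, rose by 0.78 ± 0.08. Stmn1, the most abundant member that did not pass, had a log2 fold change of 0.50 ± 0.18 (adjusted p = 0.0632, edgeR, Benjamini-Hochberg). The list had a camera adjusted p = 0.000252, and an adjusted p = 0.209 with an estimated correlation. Shtn1, which encodes shootin 1, a protein of axon outgrowth, rose from 205 ± 2.65 to 335 ± 13.2 CPM (log2 fold change 0.71 ± 0.07, adjusted p = 0.000647, edgeR, Benjamini-Hochberg). Of 15 genes of the axon initial segment, 11 rose and none fell (11 and 1 adjusted over the list alone). Cntn1, a contactin, rose by 2.26 ± 0.16, Sptbn4, beta IV spectrin, by 1.46 ± 0.13, and the sodium channel Scn2a by 1.83 ± 0.18. Ank3, the ankyrin G gene, had 0.30 ± 0.13 (adjusted p = 0.108). The camera adjusted p was 6.88e-06, and the adjusted p = 0.26 with an estimated correlation. Axon guidance ligands and receptors had 18 of 38 members higher and 5 lower (19 and 5 adjusted over the list alone), among them the netrin receptor Unc5c at 2.13 ± 0.13 and Plxnd1, a plexin, at 1.07 ± 0.08. Plxna2 had 0.30 ± 0.15 (adjusted p = 0.155). The guidance list had a camera adjusted p = 0.000965, an adjusted p = 0.589 with an estimated correlation, and 0.0747 once the trend with transcript length was removed.

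Synaptic and channel genes followed the same direction. Of 30 genes for glutamate receptors and postsynaptic scaffolds, 25 rose and 0 fell (26 and 0 adjusted over the list alone) by the edgeR quasi-likelihood test, and all 30 fold changes were positive. Camk2a rose by 2.16 ± 0.11, Camk2b by 1.90 ± 0.11 and the scaffold gene Dlgap1 by 1.98 ± 0.13 on the log2 scale, while Gria2 had 0.53 ± 0.20 (adjusted p = 0.0772, edgeR, Benjamini-Hochberg). The list had a camera adjusted p = 1.12e-15, and an adjusted p = 0.209 with an estimated correlation. Of 27 genes of the presynaptic vesicle machinery, 20 rose and 2 fell, with the synaptotagmins Syt4 at 1.90 ± 0.09 and Syt1 at 1.55 ± 0.09. Cplx2 had -0.10 ± 0.07 (adjusted p = 0.302). The camera adjusted p was 2.86e-10, and the adjusted p = 0.106 with an estimated correlation. Of 27 voltage-gated ion channels, 20 rose and 0 fell (21 and 1 adjusted over the list alone), with the potassium channel Kcnd2 at 1.67 ± 0.11. The camera adjusted p was 3.14e-08, and the adjusted p = 0.365 with an estimated correlation. Upper-layer neuron markers rose in 9 of 12 members with 1 lower (10 and 1 adjusted over the list alone), led by Mef2c at 1.91 ± 0.10 and Rorb at 1.39 ± 0.09. Camera gave them an adjusted p = 1.04e-06, and the adjusted p = 0.209 with an estimated correlation. Interneuron markers rose in 8 of 16 members with none lower (8 and 1 adjusted over the list alone), including Sst at 1.71 ± 0.13 and Gad1 at 1.31 ± 0.14. For camera the adjusted p was 0.0059, and the adjusted p = 0.338 with an estimated correlation. Of 65 genes with exons regulated in neurons or by PTB proteins, 40 rose and 5 fell in total expression (41 and 5 adjusted over the list alone; camera adjusted p = 6.64e-08, adjusted p = 0.342 with an estimated correlation).

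Progenitor and proliferation genes fell. All 12 intermediate progenitor markers fell, among them Nhlh1 (-2.16 ± 0.12) and Eomes (-1.21 ± 0.07), with a camera adjusted p = 5.84e-12 and an adjusted p = 0.106 with an estimated correlation. Of 26 cell cycle genes, 25 fell, such as Cenpe (-1.34 ± 0.07), Ccnb1 (-1.12 ± 0.07) and Tpx2 (-1.12 ± 0.07), with a camera adjusted p = 6.29e-25 and an adjusted p = 0.106 with an estimated correlation. Of 20 radial glia markers, 13 fell and 5 rose (13 and 6 adjusted over the list alone). Prom1 (-1.06 ± 0.08), Vim (-0.94 ± 0.10) and Pax6 (-0.74 ± 0.08) were lower. The list had a camera adjusted p = 0.00941, and an adjusted p = 0.26 with an estimated correlation. Of 18 genes of the ATF4 stress response, 14 fell and 1 rose, including the serine synthesis gene Psat1 (-1.08 ± 0.07), Shmt2 (-1.05 ± 0.08) and Trib3 (-2.16 ± 0.17). The list had a camera adjusted p = 7.91e-06, and an adjusted p = 0.106 with an estimated correlation. Of the 31 lists, 0 passed camera with an estimated correlation in the DIV3 comparison (6 at an unadjusted p under 0.05), 19 passed it with the preset value, and 21 passed fry.

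Markers of cells other than neurons also moved between DIV1 and DIV3. Pericyte and fibroblast markers rose in 10 of 13 measured members (11 adjusted over the list alone), with Rgs5 at 1.32 ± 0.15 CPM (SD, n = 2) at DIV1 and 14 ± 2.84 CPM at DIV3, and Col1a1 at 1.67 ± 0.134 and 11.4 ± 1.15 CPM. Their camera adjusted p was 1.76e-05, and the adjusted p = 0.209 with an estimated correlation. Oligodendrocyte lineage markers rose in 4 of 9 members, led by Olig1 (3.50 ± 0.22) and Olig2 (3.79 ± 0.38). Their camera adjusted p was 0.0218, the adjusted p = 0.209 with an estimated correlation, and 0.058 with the length trend removed. Astrocyte markers rose in 8 of 12 members and fell in 3. Sparcl1, which neurons also express, rose by 2.39 ± 0.07, while Gja1, a gap junction gene that radial glia also express, was lower (-1.19 ± 0.08). Camera gave an adjusted p = 0.00161, and the adjusted p = 0.198 with an estimated correlation. Microglia markers fell in 3 of 13 members (1 adjusted over the list alone), including Ctss (-1.38 ± 0.23). Their camera adjusted p was 0.0283, the adjusted p = 0.621 with an estimated correlation, and 0.111 with the length trend removed. Erythroid genes fell in 7 of 8 members, with the beta globin Hbb-bs at 5.85 ± 1.77 CPM at DIV1 and 0.122 ± 0.094 CPM at DIV3. For this list camera gave an adjusted p = 4.77e-08, and the adjusted p = 0.209 with an estimated correlation. Of 5 endothelial markers measured, none passed (camera adjusted p = 0.755).

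Large increases were also found among genes with a mean of at least 5 CPM. Nwd2 rose from 1.24 ± 0.175 CPM (SD, n = 2) to 67.9 ± 0.555 CPM, a log2 fold change of 5.77 ± 0.19 (adjusted p = 5.23e-05, edgeR, Benjamini-Hochberg). Kcnj2, an inward rectifier potassium channel, rose by 4.62 ± 0.18, the guanine deaminase gene Gda by 4.41 ± 0.19, the neuropeptide Y receptor Npy1r by 4.07 ± 0.15, and Npr3, a natriuretic peptide receptor, by 3.86 ± 0.34. Rspo2, Rasgrf2 and Necab1 rose by 3.72 ± 0.40, 3.66 ± 0.17 and 3.57 ± 0.27. Besides Hbb-bs (-5.80 ± 0.43) and Hbb-y (-2.94 ± 0.54), large decreases were in Phyh (-3.14 ± 0.14), the progenitor gene Hmga2 (-2.87 ± 0.22), the tubulin gene Tuba1c (-2.79 ± 0.22), the imprinted RNA H19 (-2.73 ± 0.23) and Dhrs4 (-2.58 ± 0.18). Hbb-bs, Hbb-y and Tuba1c have close copies with which they share reads, so their values are uncertain. The other lists passed in neither direction by camera. Of 27 splicing regulators, 6 rose and 6 fell (8 and 8 adjusted over the list alone), with Rbfox1 at 1.17 ± 0.09, Celf4 at 0.79 ± 0.07 and Msi1 at -0.68 ± 0.07. Of 11 deep-layer markers 3 rose and 4 fell (3 and 5 adjusted over the list alone), with Ldb2 at 1.91 ± 0.08 and Tbr1 at -0.62 ± 0.08. Median and mean log2 fold change differed in sign for the splicing regulators (-0.09 and 0.01), the deep-layer markers (-0.06 and 0.05) and the Cajal-Retzius markers (-0.28 and 0.04), of which 3 of 10 rose and 2 fell. Camera and fry differed in sign for the splicing regulators and for the sex-linked genes, of which none of 5 passed. Of 18 hypoxia and glycolysis genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone), with Hk1 at 1.03 ± 0.07 and Hk2 at -1.15 ± 0.10. Their camera adjusted p was 0.0625, and 0.0466 with the length trend removed. The counts higher and lower were 2 and 4 of 14 immediate early genes (3 and 4 adjusted over the list alone), Egr1 among the latter (-1.67 ± 0.12), 4 and 5 of 23 cholesterol synthesis genes, and 2 and 5 of 18 p53 and apoptosis genes (2 and 6 adjusted over the list alone). They were 1 and 1 of 11 heat shock genes, 0 and 3 of 14 serum response factor targets, and 2 and 0 of 7 mitochondrially encoded genes. Apart from the hypoxia and glycolysis list, the camera adjusted p of these lists lay between 0.107 for the serum response factor targets and 0.931 for the splicing regulators and the sex-linked genes.

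By the main test, isoform usage changed from DIV1 to DIV3 in Tpm1, Celf2, Elavl1 and Clta, among other genes. With the replicate number as a block, the calls of Celf2, Clta, Gad1, Satb1, Eef1d and Adamtsl1 ended. The share of Tpm1-209, a tropomyosin 1 transcript of 8 exons, rose from 28.7% ± 0.85 (SD, n = 2) to 54.7% ± 4.81. Celf2-206, from the gene of an RNA binding protein, fell from 52.1% ± 0.819 to 19.9% ± 0.203, and Elavl1-201 rose from 80.6% ± 0.783 to 98.3% ± 0.181. The clathrin light chain transcript Clta-206 fell from 13.8% ± 4.26 to 1.72% ± 0.519. Eef1d-204 rose from 57.5% ± 1.24 to 67.6% ± 2.49. The tests for Tpm1, Celf2, Elavl1, Clta and Eef1d gave adjusted p = 2.38e-05, 0.0196, 0.00179, 0.00369 and 0.0152 (edgeR diffSpliceDGE, Simes, Benjamini-Hochberg). Fgfr1op2-204, at 39.6% ± 6.46 of its gene at DIV1, was estimated at 0 counts in both DIV3 libraries (adjusted p = 8.32e-07), and was called without any of the 6 libraries (highest adjusted p = 0.00166). Adamtsl1-209 went from 62.6% ± 11.5 to 0 (adjusted p = 0.00961), in a gene with a mean of only 101 expected counts per library. Of 7496 genes with 21086 transcripts, 32 were called by edgeR diffSpliceDGE, 125 by its F test and 72 by limma's diffSplice, and these 7 genes passed all 3 tests. A limma test on log ratios of shares, added after the data were seen, called 0 (624 at an unadjusted p under 0.05), with adjusted p between 0.0882 and 0.514 for the 9 called genes given with shares. The power of this log-ratio test was not simulated. Elavl1 and Eef1d lie outside the rule for named genes and were chosen, after their values were seen, for passing the first 3 tests. Gad1-201, which rose from 48.4% ± 0.299 to 95.4% ± 1.64, and Satb1-208, from 0.294% ± 0.373 to 40.6% ± 24.8, passed the first and the F test (Simes adjusted p = 0.0395 and 0.031). Shtn1-202 (chromosome 19, 58973356 to 59076069, 15 exons) made up 32.8% ± 2.96 of Shtn1 at DIV1 and 75.2% ± 2.95 at DIV3, the rest being Shtn1-201 with 17 exons. The Simes test did not call Shtn1 (adjusted p = 0.122), while the F test and limma's diffSplice did (adjusted p = 0.00212 and 0.00291). Dlg4, which encodes the postsynaptic scaffold PSD-95, had Dlg4-203 at 68.4% ± 3.71 and 69% ± 0.212 and was not called (adjusted p = 1).

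Of 53 tested genes of the list of regulated exons, 2 were called at DIV3, Tpm1 and Clta (3 adjusted over the list alone), 3.77% against 0.403% of other genes (Fisher's exact test, two-sided, p = 0.0212). The other genes were not matched to the list for expression, which bears on the power to call a gene. In 10 of the 32 called genes (31.2%) the transcript with the largest change was estimated at 0 in a group, against 1.88% of uncalled genes. At an unadjusted p under 0.05 there were 306 genes, where chance gives 375. The count was 54 without DIV3 replicate 2, 64 without knockout replicate 1 and 59 without knockout replicate 2. In 100 simulated data sets with no change, a mean of 6.26 genes and at most 16 were called. Of the 9 called genes given with shares, Fgfr1op2 was called without each library. Tpm1 had an adjusted p = 0.219 without wild-type DIV1 replicate 2, and Elavl1 0.0644 without DIV3 replicate 1 (edgeR diffSpliceDGE, Benjamini-Hochberg), and both were called without each other library. Eef1d was not called without wild-type DIV1 replicate 1 or 2 or DIV3 replicate 1 (adjusted p = 0.108, 0.267 and 0.829). Clta, Celf2, Gad1 and Adamtsl1 were not called without any of the 4 wild-type libraries, with the adjusted p between 0.0595 (Adamtsl1, without DIV3 replicate 2) and 0.517 (Clta, without wild-type DIV1 replicate 1). Satb1 was not called without any of the 6 libraries (adjusted p between 0.0745 and 0.567). Shtn1 was called without knockout replicate 1 or 2 (adjusted p = 0.0129 and 0.0143).

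The second comparison asked what differs at DIV1 between wild type and the libraries labelled Ptbp2 knockout. For total expression, no gene passed the edgeR quasi-likelihood test (0 of 16847 genes). There were 2475 genes at an unadjusted p under 0.05, where chance gives 842, and 21 at an adjusted p under 0.1, 7 higher and 14 lower. Among the genes with the smallest p, chosen after their values were seen, were Flna, Dlg4, Sla and Cdkl2. Flna (chromosome X, 74223461 to 74249820), the actin crosslinker filamin A, was at 383 ± 4.02 CPM (SD, n = 2) in wild type and 177 ± 18.9 CPM in the knockout (log2 fold change -1.11 ± 0.09, adjusted p = 0.059, edgeR, Benjamini-Hochberg). Dlg4 was at 158 ± 2.04 and 235 ± 3.29 CPM (0.57 ± 0.07, adjusted p = 0.0886). The adaptor gene Sla had -0.83 ± 0.08 and the kinase gene Cdkl2 -1.62 ± 0.15, both with an adjusted p = 0.059. Shtn1 had -0.22 ± 0.07 (adjusted p = 0.333), or -0.12 ± 0.06 with the length trend removed.

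The tools differed on the knockout comparison. DESeq2 called 204 genes (44 higher, 160 lower), Flna, Dlg4, Sla and Cdkl2 among them, and limma-voom called 0. With no expression filter, edgeR called 1061 genes (508 higher, 553 lower). It called 43 without knockout replicate 1 and 5549 without knockout replicate 2. With the length trend removed, a fit added after the data were seen, 26 genes were called, 9 higher and 17 lower. Flna then had -0.87 ± 0.06, Sla -0.81 ± 0.06, Cdkl2 -1.53 ± 0.12 and Dlg4 0.60 ± 0.05 (each adjusted p = 0.0134, edgeR, Benjamini-Hochberg). With the replicate number, which the sex-linked genes follow in every group, as a block in the same fit, 0 genes were called (1598 at an unadjusted p under 0.05), and each of these 4 had an adjusted p = 0.0837 (edgeR, Benjamini-Hochberg). The block is a single term for all 3 groups, while the knockout replicates differed, on balance, in the opposite direction to the wild-type pairs.

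As lists, genes of the ATF4 stress response rose in the knockout and several neuronal lists fell by camera, while none of their members passed alone. The ATF4 list had 15 of 18 members positive, with a median of 0.37 (10 higher adjusted over the list alone), among them Trib3 at 0.57 ± 0.15, Shmt2 at 0.39 ± 0.08 and Psat1 at 0.30 ± 0.07. Its camera adjusted p was 5.72e-08 and 9.44e-09 with the length trend removed, and the adjusted p = 0.289 with an estimated correlation. Cell cycle genes rose as a list, with a median of 0.13 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00374, 6.05e-05 with the length trend removed, adjusted p = 0.588 with an estimated correlation). Deep-layer neuron markers fell, 10 of 11 negative with a median of -0.30 (5 lower adjusted over the list alone), with Tbr1 at -0.29 ± 0.08 (-0.19 ± 0.07 with the length trend removed) and Ldb2 at -0.39 ± 0.08. Their camera adjusted p was 2.26e-05 and 5.34e-05 with the length trend removed, and the adjusted p = 0.588 with an estimated correlation. Ion channels fell, 26 of 27 negative (median -0.31, none adjusted over the list alone; camera adjusted p = 5.72e-08, 0.0363 with the length trend removed, adjusted p = 0.588 with an estimated correlation). Oligodendrocyte lineage markers had 7 of 9 members negative (median -0.27, 1 lower adjusted over the list alone; camera adjusted p = 0.0113, 0.0363 with the length trend removed, adjusted p = 0.588 with an estimated correlation).

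For 6 further lists the camera call in the knockout ended once the length trend was removed. Axon guidance genes had 35 of 38 members negative, with a median of -0.23 (6 lower adjusted over the list alone) and Plxna2 at -0.36 ± 0.15, or -0.06 ± 0.06 without the trend (camera adjusted p = 5.72e-08, 0.134 without the trend, adjusted p = 0.588 with an estimated correlation). Genes of the axon initial segment had a median of -0.22 and Ank3 at -0.42 ± 0.13, or -0.16 ± 0.06 without the trend (0.00038 and 0.138, adjusted p = 0.588 with an estimated correlation). Glutamate receptor and scaffold genes had a median of -0.24 and Gria2 at -0.48 ± 0.20, or -0.25 ± 0.11 without the trend, while Dlg4 was the 1 member higher adjusted over the list alone (0.000123 and 0.437, adjusted p = 0.588 with an estimated correlation). Upper-layer markers had a median of -0.19 (0.0143 and 0.718), genes with regulated exons -0.10 (0.000283 and 0.495; 1 higher and 3 lower adjusted over the list alone), and erythroid genes 0.84 (0.00157 and 0.0866; 3 higher adjusted over the list alone), with Hbb-bs at 0.80 ± 0.26, or 0.48 ± 0.25 without the trend. These 3 lists also had an adjusted p = 0.588 with an estimated correlation. Cholesterol synthesis genes passed only with the trend removed (median 0.08 before removal, camera adjusted p = 0.12 and 0.0363). In the knockout 0 lists passed fry (lowest adjusted p = 0.0663, for the ATF4 list) or camera with an estimated correlation (1 at an unadjusted p under 0.05), against 11 by camera with the preset value. The medians of the lists that did not pass lay between -0.28 (Cajal-Retzius markers) and 0.30 (endothelial markers). Median and mean differed in sign for microtubule and neurofilament genes (0.02 and -0.02), microglia markers (0.08 and -0.01) and radial glia markers (0.04 and -0.00), and interneuron markers had -0.09 and 0.00.

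By the main test, isoform usage differed between wild type and knockout in Clip2, Dnm1, Camk2b and Arhgef7, among other genes. With the replicate number as a block, the calls of Clip2, Snap91, Cald1, Gtf2a2 and Adamtsl1 ended. Clip2-202, from a microtubule binding protein gene, rose from 34.8% ± 2.14 (SD, n = 2) of Clip2 in wild type to 80.4% ± 4.88 in the knockout. Dnm1-201, from the gene of the endocytic GTPase dynamin 1, rose from 8.65% ± 0.324 to 45.6% ± 5.34. Camk2b-209 (Camk2b, chromosome 11, 5969644 to 6066362) rose from 69.6% ± 0.373 to 87.2% ± 0.139, and Snap91-202, from a clathrin adaptor gene, fell from 76.6% ± 0.839 to 50.4% ± 5.03. Arhgef7-202, from a guanine nucleotide exchange factor gene, fell from 40.8% ± 0.335 to 25.1% ± 5.36. Flna-213, a transcript of 47 exons annotated as a target of nonsense-mediated decay, rose from 28.5% ± 7.35 to 56.2% ± 5.47. Its estimate was uneven between the 2 wild-type DIV3 libraries, at 1.59% and 32.5%. The adjusted p was 0.0176 for Clip2, 0.02 for Dnm1, 0.00122 for Camk2b, 0.0452 for Snap91, 0.000873 for Arhgef7 and 0.033 for Flna (edgeR diffSpliceDGE, Simes, Benjamini-Hochberg). Tpm1-205 was at 0 in both wild-type DIV1 libraries and at 16.4% ± 2.75 in the knockout (adjusted p = 2.07e-06). Emc1-204, also annotated for nonsense-mediated decay, rose from 2.12% ± 0.54 to 23.7% ± 4.52, and Gtf2a2-203 from 2.17% ± 0.662 to 20.5% ± 11.3 (adjusted p = 0.0087 and 0.0216). Adamtsl1-209, of a gene with a mean of only 101 expected counts per library, went from 62.6% to 0 (adjusted p = 0.0126). Cald1-203 fell from 65.8% ± 5.16 to 37.1% ± 18.4 and Nr4a2-201 from 77.3% ± 0.896 to 41.7% ± 20.9, with a wide spread between the knockout libraries (adjusted p = 0.00785 and 0.00241).

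**Figure D3:**
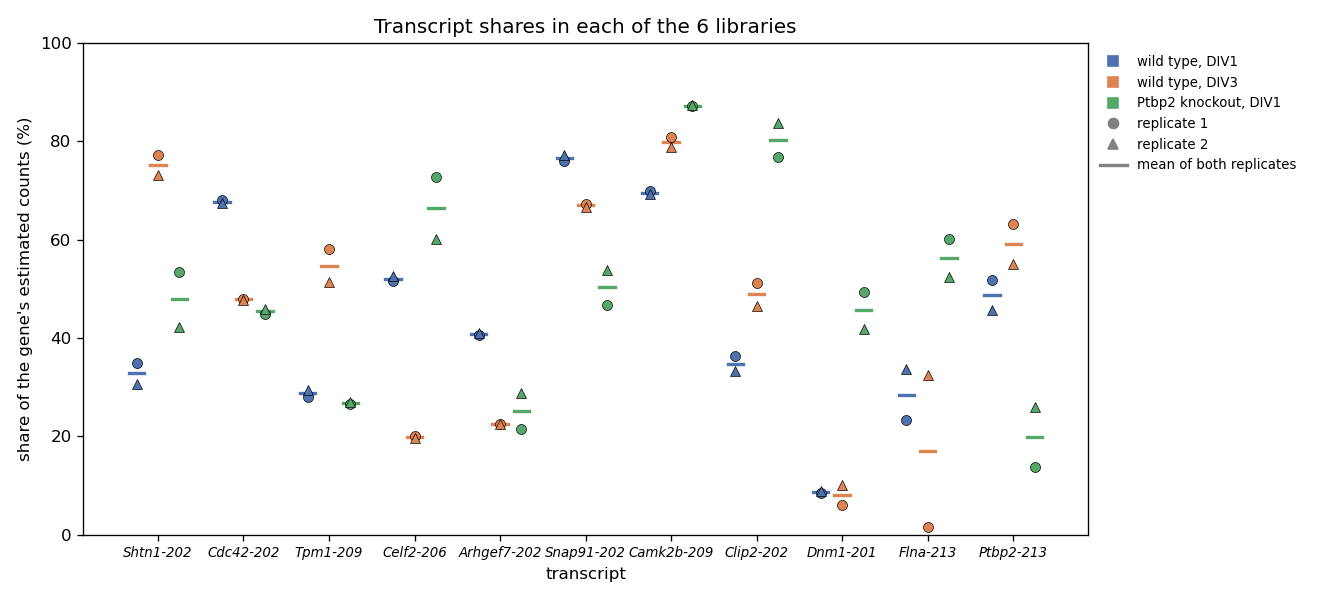
Share of the gene's expected counts (vertical axis, percent) for 11 transcripts in each of the 6 libraries, with colours for groups, symbols for replicates and a line for the mean of both replicates. Shtn1-202 rose from 32.8% to 75.2% at DIV3 and was at 47.8% in the knockout, and Clip2-202 was at 34.8%, 48.8% and 80.4%.

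In all, 43 genes were called for isoform usage in the knockout by edgeR diffSpliceDGE, 102 by its F test and 29 by limma's diffSplice. The limma test on log ratios of shares called 0 (521 at an unadjusted p under 0.05), with adjusted p between 0.285 and 0.597 for the 12 called genes given with shares. Camk2b, Clip2, Dnm1, Emc1 and Gtf2a2 passed the other 3 tests, for which Emc1 and Gtf2a2, outside the rule for named genes, were chosen after their values were seen. Other transcript filters ended some of these calls. With no minimum share, the adjusted p was 0.199 for Camk2b, 0.115 for Dnm1 and 0.301 for Gtf2a2, and with the stricter filter 1 for Camk2b, 0.054 for Clip2 and 0.0617 for Gtf2a2 (edgeR diffSpliceDGE, Benjamini-Hochberg). Dnm1 had 0.195 with only the 4 libraries compared. Of 53 tested genes with regulated exons, 5 were called, Tpm1, Arhgef7, Camk2b, Flna and Snap91 (7 adjusted over the list alone), 9.43% against 0.511% of other genes (Fisher's exact test, two-sided, p = 1.14e-05). As at DIV3, the other genes were not matched for expression, so this does not single out regulated exons. Shtn1-202 was at 47.8% ± 7.84 in the knockout (adjusted p = 1), between its wild-type levels at DIV1 and DIV3. Dlg4-203 was at 74.6% ± 1.65 against 68.4% ± 3.71 (adjusted p = 1). Dlg4-205, annotated for nonsense-mediated decay and under the 5% share needed for the test, was at 2.58% ± 0.0753 in wild type at DIV1, 1.33% ± 0.228 at DIV3 and 0.525% ± 0.0945 in the knockout, and was chosen after its values were seen. In 17 of the 43 called genes (39.5%) the transcript with the largest change was at 0 in a group, against 2.11% of uncalled genes. The SD of the share difference between replicates was 14.0 points in the knockout, against 7.36 and 8.46 in wild type at DIV1 and DIV3, and in 28 of the 43 called genes the gaining transcript was the shorter. In simulated data sets with no change, a mean of 6.32 genes and at most 19 were called. There were 368 genes at an unadjusted p under 0.05, where chance gives 375, and the count of called genes was 18 without wild-type DIV1 replicate 1 and 706 without knockout replicate 2. Among the 12 called genes given with shares, leaving out wild-type DIV1 replicate 1 or 2 ended 11 and 10 calls, DIV3 replicate 1 or 2 ended 6 each, and knockout replicate 1 or 2 ended 5 and 2. Camk2b had an adjusted p = 0.0889 and Arhgef7 of 1 without wild-type DIV1 replicate 1, and Tpm1 of 0.0507 without wild-type DIV1 replicate 2 (edgeR diffSpliceDGE, Benjamini-Hochberg), and these 3 genes were called without each other library. The highest adjusted p over the 6 fits was 0.416 for Clip2, 0.399 for Dnm1, 0.69 for Emc1, 0.683 for Flna, 0.187 for Adamtsl1 and 0.0787 for Nr4a2, and 1 for Snap91, Cald1 and Gtf2a2.

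The third comparison asked whether the knockout at DIV1 shifts transcripts the way 2 more days in culture do. At the level of isoforms, the transcript with the largest DIV3 difference was followed in each of the 53 tested genes of the list of regulated exons, a tally added after the data were seen. Its share differed in the same direction in the knockout in 27 genes (50.9%), against 45.9% of other genes (Fisher's exact test, two-sided, p = 0.491). Simulated data with no change gave 71.3% for the list. All groups had the same dispersion there, which may overstate what the shared DIV1 libraries give. With separate DIV1 libraries the observed share was 47.2% and 43.4%. A lasting difference between DIV1 replicates enters the 2 contrasts with opposite sign there, which can lower this share. Single genes with the same direction are given as values. Arhgef7-202 was at 22.6% ± 0.0384 (SD, n = 2) at DIV3 and 25.1% in the knockout, against 40.8% at DIV1, and Cdc42-202, from a small GTPase gene, at 47.9% ± 0.0998, 45.4% ± 0.744 and 67.8% ± 0.518. Cdc42 was called by the F test and limma's diffSplice in both contrasts and not by the Simes test (adjusted p = 1 for both), and was chosen after its values were seen. Camk2b-209 was at 79.9% ± 1.45 at DIV3 and Snap91-202 at 66.9% ± 0.518, with the knockout beyond DIV3 for both. The DIV3 differences of Arhgef7, Camk2b and Snap91 did not pass (adjusted p = 1, 1 and 0.647, edgeR diffSpliceDGE, Benjamini-Hochberg). Celf2-206 and Tpm1-209 did not follow, with 66.4% ± 8.91 and 26.7% ± 0.256 in the knockout. Called in both contrasts were 8 genes, Dusp3, Brd8, Rgs17, Stra6l, Tpm1, Mettl25, Endov and Adamtsl1, against 0.184 for independent lists and a mean of 1.34 (highest 5) in 100 simulated data sets with no change. In 7 of the 8 the transcript with the largest summed change moved the same way in both, and in 4 it was at 0 in both wild-type DIV1 libraries. Stra6l and Adamtsl1 had means of only 58 and 101 expected counts per library, so their shares rest on few reads. Choice by summed change favours transcripts that move the same way, so the 7 are no test of a shared direction. In simulated data sets with any gene called in both, a mean of 1.941 and at most 5 moved the same way. Part of the excess of genes called in both may come from the shared controls. Dusp3, Rgs17, Stra6l and Mettl25 were called in neither contrast without wild-type DIV1 replicate 1 or 2 (adjusted p between 0.0697 and 0.712, edgeR diffSpliceDGE, Benjamini-Hochberg), nor at DIV3 without knockout replicate 1 or 2. Without DIV3 replicate 2, Dusp3, Stra6l and Mettl25 were not called at DIV3 and Stra6l not in the knockout, where Stra6l was also not called without knockout replicate 2. Brd8 and Endov were called at DIV3 without each library. Without knockout replicate 1, neither they nor Dusp3, Rgs17, Stra6l or Mettl25 were called in the knockout, and Brd8 was not called there without wild-type DIV1 replicate 2 either.

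The simulated data sets gave all groups the same dispersion and held no DIV3 change. Knockout replicates differed more than wild-type DIV1 replicates, with an SD of 14.0 against 7.36 points for shares and 0.34 against 0.18 for genes. Simulated values may therefore overstate what the shared DIV1 libraries give, and observed values below them decide nothing. Across all tested transcripts, the share changes of the 2 contrasts had a Pearson correlation of 0.146 and a covariance of 14.976, against 0.505 and 43.311 in simulated data with no change. With DIV1 replicate 1 used for one contrast and replicate 2 for the other, the correlation was -0.056 and -0.229. Such separate controls are not neutral either. A lasting difference between replicates 1 and 2, such as sex, enters the 2 contrasts with opposite sign, which can lower the correlation at both levels. The isoform correlation was 0.404 and 0.444 without wild-type DIV1 replicate 1 or 2, 0.240 without DIV3 replicate 1, 0.303 without knockout replicate 1 and 0.091 without knockout replicate 2. At the gene level the Pearson correlation was -0.057, the Spearman correlation -0.143 and the covariance -0.018, against 0.511, 0.470 and 0.042 in simulated data. With separate controls the correlations were -0.140 and -0.216. The gene-level correlation was 0.170 without wild-type DIV1 replicate 1, 0.246 without replicate 2, 0.013 without DIV3 replicate 1, 0.024 without knockout replicate 1, 0.010 with the length trend removed, and -0.250 over genes with a mean log2 CPM above 2, a subset chosen after the data were seen. At an unadjusted p under 0.05 in both contrasts, 161 genes were higher in both (simulated 99.8, independent lists 300) and 211 lower in both (78.5 and 272). Another 480 were higher at DIV3 and lower in the knockout (1.39 and 294), and 339 lower at DIV3 and higher in the knockout (1.77 and 278). Both contrasts carried a length trend, of opposite sign. Gap43, Mapt and Syt4, which rose at DIV3, had 0.09 ± 0.10, -0.14 ± 0.10 and -0.14 ± 0.08 in the knockout, and Eomes and Psat1, which fell, had 0.04 ± 0.07 and 0.30 ± 0.07. With the length trend removed, the knockout values were -0.09 ± 0.08 for Gap43, 0.04 ± 0.10 for Mapt, -0.04 ± 0.07 for Syt4, 0.10 ± 0.06 for Eomes and 0.27 ± 0.05 for Psat1, so the sign turned for Gap43 and Mapt. Of the genes with the smallest p in the knockout, Flna and Dlg4 changed at DIV3 with the sign they had in the knockout (-0.68 ± 0.09 and 0.35 ± 0.07; Dlg4 was not called without any of the 4 wild-type libraries, adjusted p between 0.0546 and 0.0948, edgeR, Benjamini-Hochberg), while Sla and Cdkl2 rose at DIV3 (2.18 ± 0.08 and 1.66 ± 0.14) and had negative values in the knockout.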

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

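The fits that removed the trend with length or GC content, the test on log ratios of shares and the subset of genes above a log2 CPM of 2 were chosen after seeing the data, and the other alternatives were fixed before. From DIV1 to DIV3, 6088 genes were called by edgeR, 1778 with a minimum fold of 1.5, and from 2743 to 8698 with a library left out. The other alternatives gave counts within 1.5 times, the block on the replicate number 4702. Ptbp1, Msi1, Pax6, Tbr1, Flna, Dlg4 and Shtn1 lost their call with the minimum fold.

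In the knockout, 0 genes were called, against 204 by DESeq2, 1061 without the filter, 26 with the length trend removed, 34 with the length and GC trend removed, and 0 to 5549 with a library left out. The cause of these differences was not tested. Fits without knockout replicate 2, here and for isoforms, left replicate 1 alone for the knockout, the library with the largest length trend (Spearman -0.65). By camera, 19 lists passed for DIV3 and 11 for the knockout. With an estimated correlation 0 and 0 passed, by fry 21 and 0, with the length trend removed 17 and 6, and with the block 19 and 12.

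For isoforms, the DIV3 count of 32 became 125 by the F test, 72 by limma's diffSplice, 14 at a minimum of 20 points, 63 with no minimum share, 14 with the stricter filter, 93 with only the 4 libraries compared, 0 on log ratios, and 29 to 64 with a library left out. The knockout count of 43 became 102 by the F test, 74 with no minimum change, 26 at 20 points, 94 with no minimum share, 12 with the stricter filter, 0 on log ratios, and 18 to 706 with a library left out. Dlg4-201 changed by 1.3 points at DIV3 and by -0.87 without wild-type DIV1 replicate 2 (range -0.87 to 3.47). The stricter filter also ended the calls of Clta, Gad1, Eef1d, Rgs17 and Mettl25 at DIV3, and of Flna, Camk2b, Clip2, Snap91, Arhgef7, Cald1, Gtf2a2, Rgs17 and Mettl25 in the knockout (adjusted p between 0.054 and 1, edgeR diffSpliceDGE, Benjamini-Hochberg). No minimum share ended those of Eef1d at DIV3 and of Camk2b, Dnm1, Snap91 and Gtf2a2 in the knockout (between 0.115 and 0.379), and using only the 4 libraries those of Dusp3 and Mettl25 at DIV3 and of Dnm1 and Snap91 in the knockout (between 0.0626 and 0.195). The cause was not tested, except that fewer genes were tested with the stricter filter (5137 against 7496).

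The gene-level correlation of the contrasts, -0.057, was -0.180 with the stricter filter, -0.140 and -0.216 with separate controls, 0.010 with the length trend removed, -0.250 over genes with a mean log2 CPM above 2, and -0.074 to 0.246 with a library left out (0.170, 0.246, 0.013 and 0.024 were positive). The isoform correlation, 0.146, was -0.068 with the stricter filter, -0.056 and -0.229 with separate controls, and 0.091 to 0.444 with a library left out. The sign changed with the setting at both levels. With separate controls, a lasting difference between DIV1 replicates enters the contrasts with opposite sign, which can lower the correlation.

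The main fits did not take the replicate numbers as pairs. Differences between replicates 1 and 2 correlated at 0.67 between the wild-type groups (0.54 over autosomal genes). With the knockout they correlated at -0.16 for wild type at DIV1 and -0.29 at DIV3. A shared replicate difference was thus seen between the wild-type groups, while the knockout pair differed, on balance, in the opposite direction. The block fits a single replicate term to all 3 groups, so it does not describe the knockout pair, and it leaves fewer residual degrees of freedom. The fall from 6088 to 4702 genes at DIV3, and the calls that ended with the block, therefore cannot be put down to pairing alone. With the number as a block, the isoform counts were 20 for DIV3 and 42 for the knockout, 18 and 23 of them among those called without the block. Among the called genes named for isoforms, the block ended the calls of Clta, Celf2, Gad1, Satb1, Eef1d, Adamtsl1, Dusp3, Rgs17, Stra6l and Mettl25 at DIV3 (adjusted p between 0.0606 and 0.409) and of Clip2, Snap91, Cald1, Gtf2a2, Adamtsl1, Dusp3, Rgs17 and Mettl25 in the knockout (between 0.0516 and 0.217, edgeR diffSpliceDGE, Benjamini-Hochberg). At gene level the block gave 0 knockout genes, with or without the length trend. In the simulations, 80.6% and 83.6% of 2-fold gene changes were recovered for DIV3 and the knockout, and at the estimated spread 39% and 35% of 10-fold isoform changes. Over all alternatives, named genes at DIV3 stayed on their side of the threshold, called or not, 1276 times, gained a call 27 times and lost one 11 times. In the knockout, where none was called, they stayed so 347 times and gained a call 49 times. Named isoforms, called or not, stayed on their side 167 times, gained a call 8 times and lost one 92 times at DIV3, and 208, 3 and 117 times in the knockout.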

Other observations

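Tests of the length trend, of its removal, of sex and of the position on chromosome 3 were chosen only after the result was seen, and the others were set before.

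Replicates of every group differed in sex-linked genes. Xist was at 1849, 1785 and 1212 CPM in replicate 1 of wild type at DIV1, wild type at DIV3 and knockout, and at most 1.51 in replicate 2. The Y-linked gene Ddx3y was at most 0.07 in replicate 1 and at 52.25, 47.95 and 53.3 in replicate 2, and Uty, Eif2s3y and Kdm5d followed it. The replicates of a group thus came from embryos of different sex, and sex is part of the spread behind every p-value.

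The knockout libraries differed from each other with an SD of 0.34 over genes, against 0.18 and 0.20 in the wild-type pairs. The difference followed transcript length (Spearman -0.68). Measured against the mean of all 6 libraries, the trend was largest in knockout replicate 1 (Spearman -0.65), against -0.23 in knockout replicate 2. In wild type it was 0.24 and -0.02 at DIV1 and 0.43 and 0.27 at DIV3. A technical trend in knockout replicate 1 may therefore contribute, as a hypothesis. As the whole cause the length trend is argued against by the SD of 0.28 after its removal, where the wild-type pairs had 0.17 and 0.19. As the main part of the difference, a sex effect shared by the groups is argued against, since it gives a positive correlation between pairs. The autosomal difference correlated at -0.40 with that of wild type at DIV1, and at -0.28 with the length trend removed. A smaller sex effect could not be seen. Trends with GC content of opposite sign stayed in (Spearman 0.50 in the knockout, -0.43 in wild type at DIV1). A shift of most non-neuronal cell types together is argued against, since only 1 of 6 marker lists lay beyond 0.3 after removal. That list, of pericytes and fibroblasts, was at 0.53. A different share of 1 cell type stays open, since a count over lists of unrelated cell types cannot exclude it. A batch or culture difference stays open and was not tested.

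Genes near Ptbp2 were over-represented at the lowest p of the knockout comparison (unadjusted p under 0.005). They were 20 of 271 within 20 Mb (7.38%) against 1.4% elsewhere (Fisher's exact test, two-sided, p = 4.81e-09), 8 higher and 12 lower. Fisher's test takes neighbouring genes as independent, which they need not be. The share was 17.6% within 5 Mb, 12.5% from 5 to 10, 2.79% from 10 to 20 and 0.583% from 20 to 40 Mb, and higher than in 100% of other windows. Sequence linked to the targeted allele may therefore contribute, as a hypothesis. The length trend is argued against (ratio 5.83 after its removal), but a region that varies in any comparison stays open, since among as many top-ranked DIV3 genes the window held 2.27 times its share (9 of 271, Fisher's exact test, two-sided, p = 0.0211), 2 of them low in both comparisons. Within 10 Mb, 4 of 92 genes were among the top-ranked DIV3 genes, against 15 of 92 at the lowest p of the knockout comparison. Strain differences near the allele were not tested.

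Flna, which did not pass the gene-level test, was at 177 CPM in the knockout against 383 in wild type while its decay-annotated transcript gained share, which may be part of a wider relation. The share of that transcript was uneven between the wild-type DIV3 libraries, at 1.59% and 32.5%. Over 158 genes whose decay-annotated transcripts gained 10 points or more, the knockout median log2 fold change with the length trend removed differed from that of other genes by -0.01 (permutation test, two-sided, p = 0.509). The relation was therefore not seen for such genes as a group. They were picked by mean share with no test, while shares differed between the knockout libraries with an SD of 14.0 points. Many may hold no real gain, so the permutation test could not exclude the relation. This test took the place of an earlier pair on the 8 genes called for isoform usage in both contrasts, whose results had been seen: 8 lay above the highest simulated number, 5, and 4 of the 8 had the leading transcript at 0 in wild type at DIV1, which left it undecided whether estimates of 0 account for them.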
